A study of Mus musculus with 9 samples.

How the data were processed

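Gene expression was measured by RNA sequencing in 9 libraries labelled as mouse bone marrow-derived macrophages, 3 each of control, hypoxia, and hypoxia combined with light and nanothylakoid units that had a coat of platelet membrane (NTU). Per the labels, RNA was extracted with TRIzol and a kit, purified mRNA was fragmented and copied with random primers, and the second strand was marked before adapters were ligated. Whether the strand was used in counting is not given in the sources used here. The values deposited by the authors are FPKM, read fragments scaled by gene length and by library total, in 1 table of 27364 genes by 9 libraries, and whether they were scaled further is not given in the sources used here. The labels name the human genome build GRCh38, while all gene identifiers in the table are mouse Ensembl identifiers. The aligner, the counting tool and the annotation release are not given in the sources used here.

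Symbols were taken from the reference tables for 27296 genes, and 68 had none. Within each gene the FPKM values are whole multiples of the value of 1 read, which allowed reads to be recovered, up to a common divisor, for all 27364 genes within a tolerance of 0.01 read. The gene lengths implied by this matched the union of exons in GENCODE M21 (mouse build GRCm38) within 1e-05 for 25470 of 27319 genes with a model, or 93.2%. The recovery was tested on simulated data, where 99.9% of 19357 genes came back and 0.393% shared a divisor. Because the build named in the labels and the identifiers differ, no coordinates are given. Recovered library totals ran from 17236585 to 18551695 reads, and the 998 genes with a mean of 1 to 1.5 FPKM had a median of 60.7 reads per library. No molecular identifiers are named in the labels.

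Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(FPKM + 1), with all 9 libraries in 1 fit and no covariate. Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 12006 in all, and called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p in the text comes from limma. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors beside FPKM are the SD of 3 libraries and errors beside log2 fold changes are limma standard errors. The comparisons were hypoxia with control, NTU with hypoxia and NTU with control, together with a moderated F test over the groups and a count of genes called in opposite directions in the steps from control to hypoxia and from hypoxia to NTU. That count was repeated with the hypoxia libraries divided between the steps (1 fit with 4 groups, 5 residual degrees of freedom), a test chosen after the result was seen.

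Of 36 gene lists fixed before the data were examined, 31 had at least 5 tested genes. They were tested with limma's camera at an inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and also with an estimated correlation and with fry. Camera compares the genes of a list with all other genes. Fry's first p tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. By fry's first p 19, 27 and 30 lists were called in the 3 comparisons, in the order above, and by its mixed p all 31 in each. The lists of chondrocyte, dendritic cell, lymphocyte, mast cell and basophil, and erythroid markers had too few tested genes. Where 2 identifiers carried the symbol of a list member, which was the case for Aldoa, the one with the higher mean FPKM was used, a choice made after the data were seen.

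The genes named in the text follow a rule fixed before the data were examined. For each comparison they are the 10 highest and 10 lowest log2 fold changes among called genes whose libraries do not overlap between the groups, so that all 3 libraries of a group lay on the same side. Genes without a symbol, predicted or clone-named genes and pseudogenes were left out, the last where a biotype was given. To these come the 3 members with the smallest adjusted p of each list, and Vegfa, Slc2a1, Hmox1, Nqo1, Il1b, Tnf, Il6, Nos2, Arg1, Mrc1, Hif1a, Epas1, Txnip, Col2a1 and Acan. Some genes that the rule selects are not reported. Other genes were chosen after their values were seen: Pfkfb4, Col1a1, Sparc, Dcn, Lum, Thy1, S100a8 and the neighbours of Pf4 and Ppbp. A list of collagen-producing cells was made after other values had been seen and before those of its members were, and the members named were picked from it afterwards.

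Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 FPKM, rescaling to TPM, median-of-ratios factors, quantile normalization, eBayes without the trend or with robust variance, a fit of the compared groups only, a replicate block, leaving out each library, a 2-fold minimum and the estimated correlation. Chosen after seeing the data were limma voom on the recovered reads and a fit of the 10587 protein-coding genes tested. The analysis was tested on simulated data, with 200 of the 12006 genes changed and those of a further list raised. Far fewer genes changed there than were called in the data, and library totals were known exactly. Errors from the scaling between libraries are therefore not covered by this test. Of genes changed 2-fold, 82% to 94% were found, of those changed 1.25-fold, 38% to 46%, and 3.18% to 5.43% of the calls were false. A raised list was called in each of the 3 comparisons, and none of 30 unchanged lists was. The simulated genes varied independently of each other, so this does not test false calls of lists whose genes move together. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.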

Results

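RNA was sequenced from 9 libraries labelled as mouse bone marrow-derived macrophages, the phagocytes that marrow precursors form in culture. The labels give 3 groups of 3 libraries. Control cells were untreated, hypoxia cells were kept for 24 hours under hypoxia, and the cells called NTU here had the same 24 hours of hypoxia combined with light and nanothylakoid units coated in platelet membrane. Thylakoids are the membranes in which the light reactions of photosynthesis take place. No group received the units, their coat or light alone, so every NTU value belongs to the combination. The series title names chondrocytes, the cells of cartilage, while all sample labels name macrophages. The labels do not say whether replicates were separate animals or cultures, so each p-value measures the spread between these libraries. Reads recovered from the deposited values came to 17793187, 17985612 and 18154237 in control replicates 1 to 3, to 18538297, 18237267 and 17438049 in hypoxia, and to 17236585, 18551695 and 18319398 in NTU. Between 11804 and 12138 genes per library reached 1 FPKM.

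Across the 12006 genes tested, 8126 differed among the 3 groups (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05). The first principal component held 62.3% of the variance and placed the NTU libraries at 34.7 to 35.9 and the other 6 between -20.9 and -14.2. The second held 18.6% and placed the control libraries at 15.4 to 16.1 and the hypoxia libraries at -18.9 to -16.2. Replicates within a group correlated at 0.990 to 0.992 over genes (Pearson r of log2 values), and genes are not independent replicates.

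**Figure D1:**
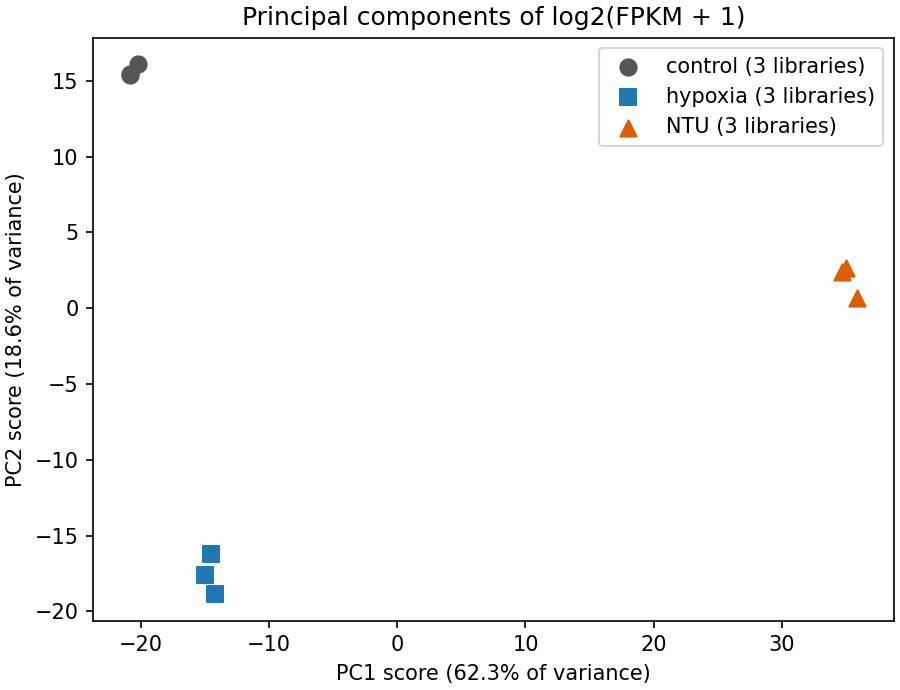
Scores of the 9 libraries on the first and the second principal component of log2(FPKM + 1), in arbitrary score units, with the percentage of variance on each axis and 1 point per library. The 3 NTU libraries sit at 34.7 to 35.9 on the first component, and the control and hypoxia libraries part on the second.

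Macrophage transcripts were abundant in every group. All 19 markers of macrophage identity reached 10 FPKM in at least 1 group mean. Csf1r, the receptor for the growth factor that sustains macrophages, stood at 447 ± 8.46 FPKM in control, 537 ± 11.3 in hypoxia and 504 ± 11.3 in NTU (mean ± SD, n = 3 per group). Transcripts known from cells that build connective tissue were abundant as well. Col1a1, a chain of type I collagen, stood at 866 ± 36.1, 857 ± 7.87 and 736 ± 23.7 FPKM in the same order, and Sparc, a matrix glycoprotein, at 383 ± 13.4, 376 ± 7.61 and 341 ± 7.87 FPKM. Of 18 stromal markers found, 10 reached 10 FPKM in each group mean and 6 in none, among the latter Dcn at 2.38 ± 0.04, 2.48 ± 0.23 and 1.93 ± 0.17 FPKM and Thy1 at 0.186 ± 0.067, 0.177 ± 0.080 and 0.335 ± 0.069 FPKM. The cartilage collagen Col2a1 stood at 7.46 ± 0.34, 7.16 ± 0.53 and 3.51 ± 0.32 FPKM. Acan, the main proteoglycan of cartilage, had 0, 3 and 2 reads in the 3 groups, too few to compare. Of 20 chondrocyte markers found in the table, 4 passed the filter on low values. The neutrophil granule gene Ngp stood at 171 ± 13.3, 145 ± 11.6 and 54.2 ± 6.50 FPKM. Col1a1, Sparc, Dcn and Thy1 were chosen for mention after their values were seen.

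The comparison of hypoxia with control shows how the libraries of cells kept for 24 hours under hypoxia differed from those of untreated cells. A difference between cultures or in the mix of cell types cannot be told apart from a response of the cells here. Genes known to be driven by the hypoxia-inducible factors (HIF) and genes of glycolysis were higher. Egln3 (ENSMUSG00000035105), an enzyme that marks HIF proteins for degradation, rose from 0.934 ± 0.327 to 36.6 ± 1.01 FPKM, a log2 fold change of 4.30 ± 0.11 (SE, n = 3 per group). Slc2a1, the main glucose transporter, rose from 16.1 ± 0.39 to 86.4 ± 1.1 FPKM (log2 2.36 ± 0.04), and Vegfa, the growth factor for blood vessels, from 17.7 ± 0.38 to 56.9 ± 1.81 FPKM (log2 1.63 ± 0.03). Genes of the mitochondrial genome were lower: mt-Nd1, a subunit of respiratory complex I, fell from 1264 ± 13.5 to 621 ± 17 FPKM (log2 -1.03 ± 0.03). The call of the mitochondrially encoded subunits as a list ended with an estimated correlation (adjusted p = 0.0726) and held in the other 22 of 23 alternatives.

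In all, 4899 genes, 40.8% of those tested, differed between hypoxia and control (limma, Benjamini-Hochberg adjusted p under 0.05), 1853 higher and 3046 lower. Of these, 138 differed at least 2-fold on the log2(FPKM + 1) scale, 119 higher and 19 lower. With a pseudocount of 0.1 in place of 1 the number was 241 (188 higher and 53 lower) and after rescaling to TPM 217 (191 and 26). By voom on recovered reads it was 250 (188 and 62), and with median-of-ratios factors 138 (127 and 11). Without hypoxia replicate 2 it was 156 (127 and 29). The share of changed genes that was higher, 37.8%, moved with the scaling between libraries, to 50.3% with median-of-ratios factors, 45.7% after quantile normalization and 55.2% after rescaling to TPM. The 10 highest included Arg1 (ENSMUSG00000019987), which splits arginine and is used as a marker of alternative activation, at 0.257 ± 0.120 against 20.9 ± 0.96 FPKM. They also included Ndufa4l2 (log2 3.63 ± 0.09), the lactate exporter Slc16a3 (3.04 ± 0.05), the mitophagy receptor Bnip3 (2.77 ± 0.06), the adenylate kinase Ak4 (2.73 ± 0.04), Ankrd37, Slco4a1, Krt19 and Apln. Among the lowest were Cemip (log2 -1.40 ± 0.06), which takes part in hyaluronan breakdown, Dcxr (-1.26 ± 0.08), the monocyte chemokine Ccl7 (-1.20 ± 0.19), Nqo1 (-1.11 ± 0.12), a quinone reductase driven by the antioxidant factor NRF2, Fst (-1.08 ± 0.09) and Spata24 (-1.23 ± 0.13). The other 4 of the lowest were genes of small RNAs, Snora47, Mir674, Mir669n and Mir301, which libraries of mRNA measure poorly. Their calls ended in 1, 9, 15 and 15 of 20 alternatives, with adjusted p-values of up to 0.0751, 0.137, 0.149 and 0.144.

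Of 21 glycolysis genes tested, 18 rose and 1 fell (19 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.47 (camera, adjusted p = 3.02e-25). Examples were Pgk1 at 245 against 893 FPKM (log2 1.86 ± 0.02), Pgam1 (1.65 ± 0.02) and Eno1 (1.47 ± 0.02). These 3 have near-identical pseudogene copies, which could not be told apart here from the gene. The member that fell was Pfkfb4 (-0.24 ± 0.05). Of 32 other HIF target genes 31 rose and none fell (31 adjusted over the list alone), with a median of 1.40 (adjusted p = 1.09e-35), Egln1 at 1.60 ± 0.03 and P4ha2, a collagen prolyl hydroxylase, at 1.95 ± 0.03 among them. The mRNA of HIF-1 alpha itself, Hif1a, fell from 17.4 ± 0.67 to 13.9 ± 0.29 FPKM, and Epas1, which encodes HIF-2 alpha, from 6.59 ± 0.12 to 4.40 ± 0.28 FPKM.

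Genes of mitochondrial respiration were lower. Of 10 mitochondrially encoded subunits 9 fell and none rose (10 fell adjusted over the list alone; median -0.90, camera adjusted p = 1.43e-07, adjusted p = 0.0726 with an estimated correlation). Of 75 nuclear-encoded subunits of oxidative phosphorylation 49 fell and 2 rose (54 and 2 adjusted over the list alone; median -0.22, adjusted p = 1.86e-08), with Ndufa12 at -0.58 ± 0.05, Ndufa5 at -0.52 ± 0.05 and Ndufv3 as one of the members that rose, at 0.48 ± 0.05. Of 19 genes of the tricarboxylic acid cycle 18 fell and none rose (18 adjusted over the list alone; median -0.23, adjusted p = 4.35e-06), among them Idh2 (-0.78 ± 0.04) and Sucla2 (-0.28 ± 0.03). Cholesterol synthesis genes fell in 20 of 22 cases and rose in none (21 adjusted over the list alone; median -0.40, adjusted p = 4.63e-08), with Hsd17b7 at -0.62 ± 0.05, Sqle at -0.43 ± 0.03 and Cyp51 at -0.50 ± 0.04.

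NRF2 antioxidant genes fell in 23 of 29 cases and rose in 1 (24 and 1 adjusted over the list alone; median -0.30, adjusted p = 4.63e-08, adjusted p = 0.179 with an estimated correlation), with Blvrb at -0.60 ± 0.03 and G6pdx, which supplies NADPH, at -0.58 ± 0.03. Hmox1, which breaks down heme, changed by -0.20 ± 0.03. Of 40 proliferation genes 26 fell and 1 rose (30 and 1 adjusted over the list alone; median -0.17, adjusted p = 2.99e-06), with Rrm2 at -0.50 ± 0.03 and Pcna, the clamp of the replication fork, at -0.41 ± 0.03. Iron handling genes fell in 9 of 15 cases and rose in none (9 fell and 1 rose adjusted over the list alone; adjusted p = 0.00484, adjusted p = 0.0726 with an estimated correlation), led by the transferrin receptor Tfrc (-1.02 ± 0.04).

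Inflammatory genes went both ways under hypoxia. Of 23 inflammatory cytokine and activation genes 8 rose and 7 fell (the same counts adjusted over the list alone; camera adjusted p = 0.501; the median was -0.07 and the mean 0.12), of 16 chemokines 4 rose and 5 fell (4 and 5 adjusted over the list alone; adjusted p = 0.792), and of 19 NF-kB feedback genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.103). The falls among the NF-kB feedback genes rested on the scaling, with 7 up and none down after rescaling to TPM and 6 up and 1 down with median-of-ratios factors. The prostaglandin synthase Ptgs2 rose from 5.22 ± 0.30 to 12.7 ± 0.87 FPKM, and Ier3 from 19.1 to 61.8 FPKM (log2 1.65 ± 0.04). Il1b stayed under 1 FPKM, at 0.252 ± 0.135 and 0.611 ± 0.205. Tnf stood at 9.64 ± 0.83 and 8.35 ± 0.53 FPKM (log2 -0.18 ± 0.06, adjusted p = 0.0382). The call of Tnf in this comparison ended in 14 of 22 alternatives (adjusted p of 0.00676 to 0.126) and that of Il1b in 7 of 22 (0.00947 to 0.129). Cd14, the co-receptor for lipopolysaccharide, rose from 80.2 ± 4.35 to 234 ± 27.4 FPKM. Of 19 macrophage markers 6 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.693), and of 15 stromal markers 1 rose and 4 fell (1 and 3 adjusted over the list alone; adjusted p = 0.511).

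In this comparison 11 of the 31 lists tested were called by camera, 4 higher and 7 lower. The 6 that held with an estimated correlation were glycolysis, other HIF targets, nuclear-encoded oxidative phosphorylation, the tricarboxylic acid cycle, cholesterol synthesis and proliferation. Their adjusted p by camera was then far larger. It was 0.000199 for other HIF targets, 0.00395 for glycolysis, and 0.021 for both oxidative phosphorylation and cholesterol synthesis. The tricarboxylic acid cycle and proliferation, at 0.047 each, lay just under the threshold. After rescaling to TPM the genes called lower numbered 11 in the tricarboxylic acid cycle and 15 in proliferation, and both lists stayed called.

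**Figure D2:**
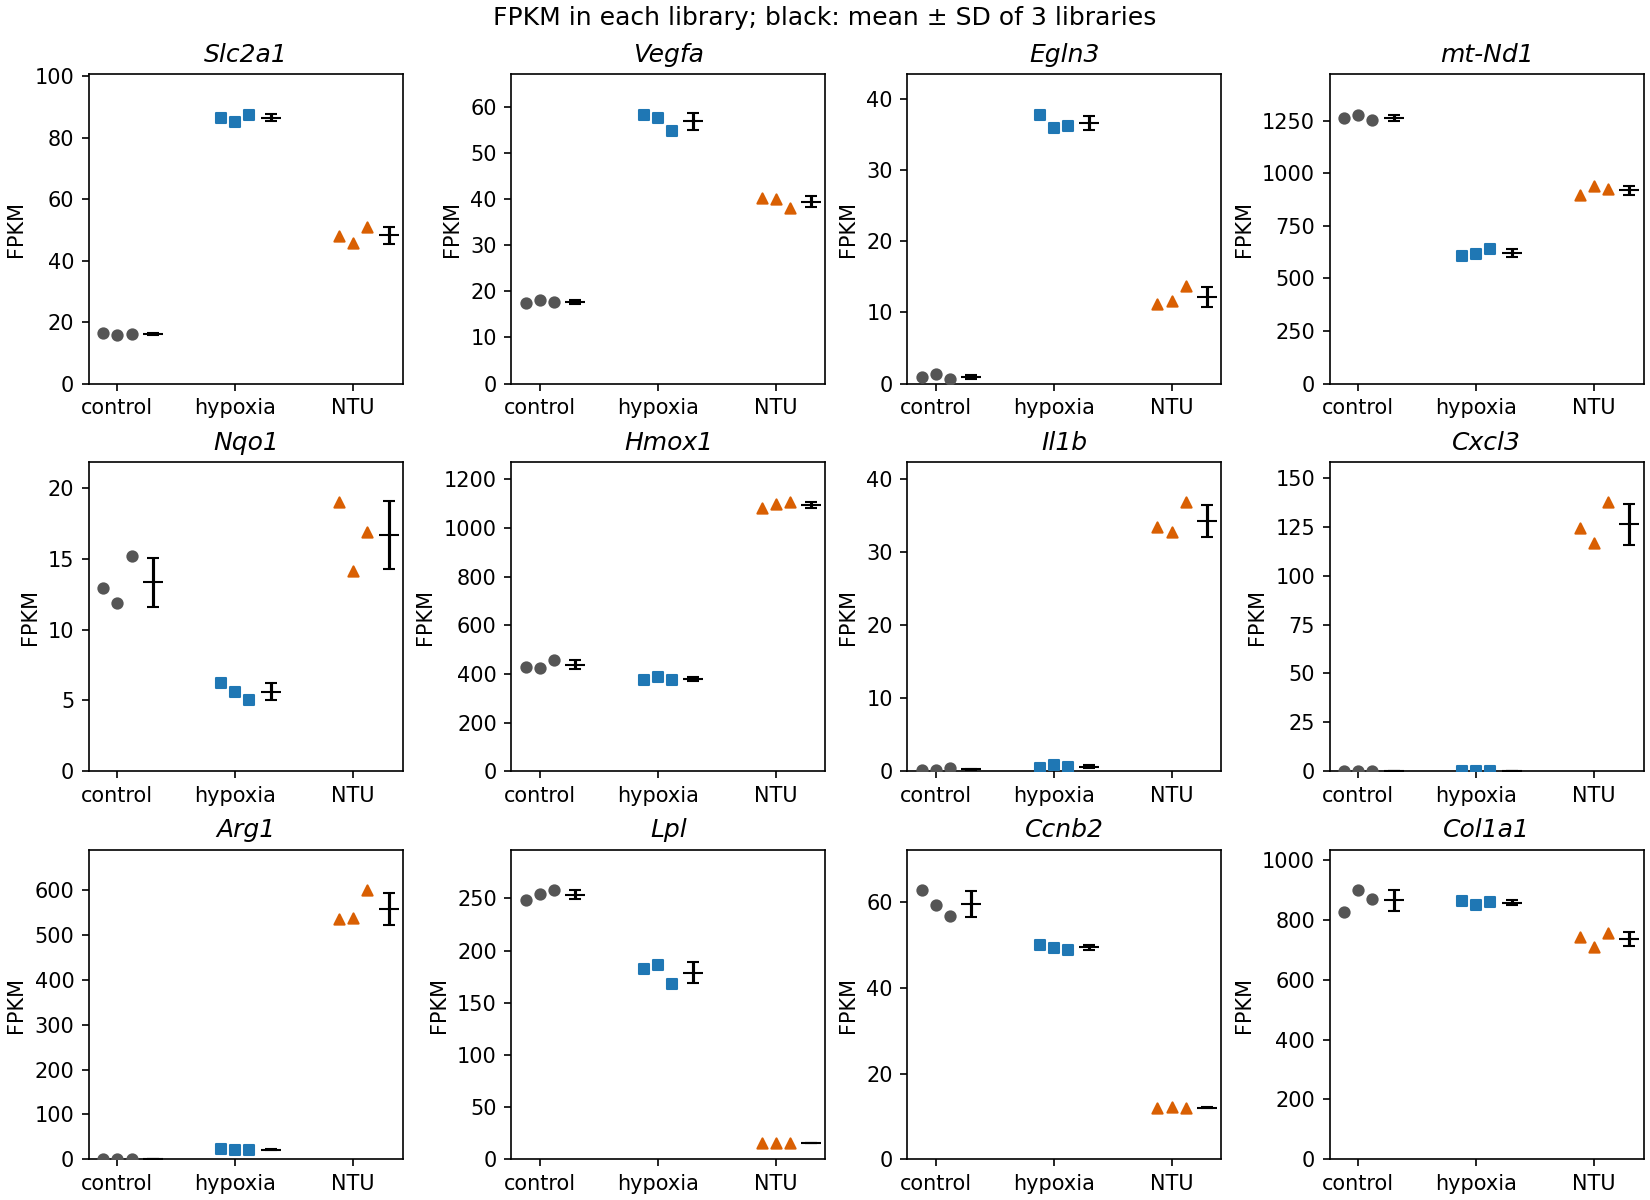
FPKM of 12 genes in each of the 9 libraries, 1 panel per gene with a linear axis from 0; coloured points are libraries, and the black mark and bar are the mean and SD of the 3 libraries of a group. Slc2a1, Vegfa and Egln3 were highest in hypoxia, mt-Nd1 and Nqo1 were lowest in hypoxia, and Hmox1, Il1b, Cxcl3 and Arg1 were highest in NTU.

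The comparison of NTU with hypoxia shows how the libraries with units and light on top of hypoxia differed from those with hypoxia alone. Inflammatory genes and chemokines were much higher and cell cycle genes lower. Saa3 (ENSMUSG00000040026), an acute phase protein of inflamed tissue, rose from 4.98 ± 0.59 to 772 ± 50.8 FPKM, a log2 fold change of 7.02 ± 0.08 (SE, n = 3 per group). Il1b, the cytokine interleukin-1 beta, rose from 0.611 ± 0.205 to 34.2 ± 2.2 FPKM (log2 4.46 ± 0.11). Ccnb2, a mitotic cyclin, fell from 49.5 ± 0.61 to 12 ± 0.12 FPKM (log2 -1.96 ± 0.04). HIF targets and glycolysis genes were lower than in hypoxia alone, and Slc2a1 fell to 48.1 ± 2.62 FPKM (log2 -0.83 ± 0.04).

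Between NTU and hypoxia 6106 genes, 50.9% of those tested, differed (limma, Benjamini-Hochberg adjusted p under 0.05), 2163 higher and 3943 lower, and 562 of them at least 2-fold, 276 higher and 286 lower. At least 2-fold changes numbered 837 with a pseudocount of 0.1 (345 higher and 492 lower), 848 after rescaling to TPM (278 and 570), 879 by voom on recovered reads (356 and 523) and 553 with median-of-ratios factors (312 and 241). The share that was higher, 35.4%, was 50.9% with median-of-ratios factors, 45.4% after quantile normalization and 17.6% after rescaling to TPM. Rescaling to TPM moved the median log2 fold change of all genes from -0.06 to -0.20 here and from -0.11 to -0.19 for NTU against control. TPM divides each value by the FPKM sum of its library. Of that sum Gm23935 held 3.99% to 7.13% in control, 2.86% to 4.87% in hypoxia and 4.18% to 7.27% in NTU. Its share was thus mostly lower in hypoxia, and the TPM results of both comparisons with the hypoxia libraries depend in part on this gene. Its ranges in control and NTU were nearly the same, so it can account for little of the TPM shift between those groups. The ferritin gene Fth1 and the lysozyme gene Lyz2, whose large rises are given below, also raised the FPKM sum in NTU. TPM without any of these genes was not tested. The 10 highest were Saa3, Cxcl3 (log2 6.75 ± 0.08) and Cxcl2 (5.09 ± 0.10), which attract neutrophils, Acod1 (5.71 ± 0.21), which makes itaconate, Serpinb2 (5.24 ± 0.07), Slpi (4.82 ± 0.11), Arg1 (4.67 ± 0.07), Il1b, the lectin receptor Clec4e (4.34 ± 0.09) and the matrix protease Mmp9 (4.22 ± 0.12). Arg1 reached 558 ± 36.3 FPKM. The lowest were Lpl (ENSMUSG00000015568), which releases fatty acids from lipoproteins, at 179 ± 9.8 against 15.4 ± 0.33 FPKM (log2 -3.45 ± 0.04), Pcp4l1 (-2.62 ± 0.10), the prostaglandin-degrading enzyme Hpgd (-2.56 ± 0.12), Krt19, Apln, Ankrd37, the small RNA gene Mir7211, Ccnb2, Kif23 (-1.94 ± 0.04) and the cell cycle inhibitor Cdkn2c (-1.92 ± 0.04).

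Of 23 inflammatory cytokine and activation genes 18 rose and 1 fell (19 and 2 adjusted over the list alone; median 1.18, camera adjusted p = 6.94e-13). Besides Saa3 and Il1b these included Marco, a scavenger receptor, at 25.0 ± 0.34 against 404 ± 4.04 FPKM and the membrane-bound protease Mmp14 (1.76 ± 0.03). Tnf rose to 20.2 ± 0.15 FPKM (log2 1.18 ± 0.06), and Nos2, the inducible nitric oxide synthase, from 0.437 ± 0.090 to 3.05 ± 0.31 FPKM. Il6 had 2 reads in the hypoxia group and 181 in NTU, at 1.39 ± 0.62 FPKM, and did not pass the filter on low values. Of 16 chemokines 14 rose and 1 fell (14 and 1 adjusted over the list alone; median 1.56, adjusted p = 1.35e-11), Ccl5 at 20.3 against 118 FPKM (2.49 ± 0.05) among them. Of 19 NF-kB feedback genes 16 rose and none fell (16 adjusted over the list alone; median 1.33, adjusted p = 5.36e-14), with Sod2, the mitochondrial superoxide dismutase, at 2.90 ± 0.05, Birc3 at 1.78 ± 0.04 and Tnfaip2 at 1.45 ± 0.04. Neutrophil markers moved apart in the same comparison: Ngp fell by 1.41 ± 0.09, Ltf fell by 1.41 ± 0.08, and S100a8 stood at 87.4 ± 9.14 and 85.5 ± 3.99 FPKM. Of 13 neutrophil markers 7 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.298), with the collagenase Mmp8 at 17.6 ± 1.69 against 218 ± 8.92 FPKM. S100a8 was chosen for mention after its values were seen.

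Interferon-stimulated genes rose in 23 of 35 cases and fell in 4 (23 and 4 adjusted over the list alone; median 0.28, adjusted p = 2.02e-05, adjusted p = 0.416 with an estimated correlation), with Ifit1 at 1.07 ± 0.06 and Oasl1 at 0.82 ± 0.06, while Ifi27l2a changed by -0.71 ± 0.04. Alternative activation genes went both ways, 5 of 16 up and 9 down (5 and 10 adjusted over the list alone; camera adjusted p = 0.62; the median was -0.21 and the mean 0.03). Arg1, Msr1 (0.89 ± 0.03) and Il4ra (0.84 ± 0.04) rose, and the mannose receptor Mrc1 fell from 152 ± 6.9 to 102 ± 7.0 FPKM (log2 -0.57 ± 0.05).

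Antioxidant genes were higher. NRF2 antioxidant genes rose in 22 of 29 cases and fell in 2 (22 and 2 adjusted over the list alone; median 0.65, adjusted p = 6.54e-14, adjusted p = 0.0676 with an estimated correlation). Hmox1 rose from 380 ± 7.42 to 1094 ± 11.8 FPKM (log2 1.52 ± 0.03), the ferritin heavy chain Fth1 from 5357 ± 252 to 17027 ± 224 FPKM, the cystine importer Slc7a11 from 1.59 to 25.6 FPKM (3.36 ± 0.08) and Nqo1 by 1.41 ± 0.12. Fth1 and the lysozyme gene Lyz2 took 1.45% to 1.49% and 1.81% to 1.90% of all reads in NTU, against 0.443% to 0.486% and 0.678% to 0.700% in hypoxia. Of 22 enzymes that make or remove reactive oxygen 14 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.39, adjusted p = 1.59e-06, adjusted p = 0.0676 with an estimated correlation), with Prdx5 at 1.40 ± 0.04 and Cybb, a subunit of the phagocyte oxidase, at 0.89 ± 0.03. Cholesterol synthesis genes rose in 18 of 22 cases and fell in none (18 adjusted over the list alone; median 0.43, adjusted p = 1.3e-09), with Hsd17b7 at 0.86 ± 0.05 and Cyp51 at 0.61 ± 0.04.

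HIF target genes were lower than in hypoxia alone. Glycolysis genes fell in 17 of 21 cases and rose in 3 (17 and 3 adjusted over the list alone; median -0.72, adjusted p = 8.61e-07), with Pdk1, which restrains pyruvate oxidation, at -1.55 ± 0.04, Pgam1 at -0.92 ± 0.02 and Tpi1 at -1.14 ± 0.03; Pfkfb3, which stimulates glycolysis, rose by 0.42 ± 0.05. Of 32 other HIF targets 28 fell and 2 rose (28 and 2 adjusted over the list alone; median -0.77, adjusted p = 4.07e-10), with Ak4 at -1.80 ± 0.04 and Egln1 at -1.16 ± 0.03. Hif1a mRNA itself rose from 13.9 ± 0.29 to 54.8 ± 1.82 FPKM (log2 1.90 ± 0.04), and Epas1 fell to 2.65 ± 0.12 FPKM. Mitochondrially encoded subunits rose in 7 of 10 cases and fell in none (7 adjusted over the list alone; median 0.35, adjusted p = 0.000216, adjusted p = 0.142 with an estimated correlation), mt-Nd1 by 0.57 ± 0.03. Nuclear-encoded subunits were not called as a list, with 7 of 75 up and 12 down (7 and 10 adjusted over the list alone; adjusted p = 0.408), nor was the tricarboxylic acid cycle, with 6 of 19 up and 5 down (6 and 5 adjusted over the list alone; adjusted p = 0.235; the median was -0.01 and the mean 0.30, since the list holds Acod1). The balance of the nuclear-encoded subunits turned with the scaling, to 22 up and 4 down with median-of-ratios factors and 2 up and 39 down after rescaling to TPM, and that of the tricarboxylic acid cycle to 8 up and 3 down and to 2 up and 10 down.

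All 40 proliferation genes fell (40 adjusted over the list alone; median -1.34, camera adjusted p = 4.17e-21), with the topoisomerase Top2a at 45.5 against 14.2 FPKM (-1.62 ± 0.03). Cytosolic ribosomal protein genes fell in 71 of 76 cases and rose in none (72 adjusted over the list alone; median -0.27, adjusted p = 2.4e-14, adjusted p = 0.108 with an estimated correlation), with Rpl3 at -0.58 ± 0.03 and Rps2 at -0.48 ± 0.02, and their median was -0.19 with median-of-ratios factors. Macrophage markers rose in 13 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone; median 0.32, adjusted p = 4.35e-05, adjusted p = 0.0958 with an estimated correlation): Lyz2 rose from 5266 ± 97.3 to 13995 ± 374 FPKM, Adgre1, the F4/80 antigen, from 439 ± 11.4 to 836 ± 8.98 FPKM and Itgam, an integrin chain, from 37.3 to 89.7 FPKM. Stromal markers fell in 10 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone; median -0.15, adjusted p = 0.0458, adjusted p = 0.391 with an estimated correlation), with Cxcl12 at -0.82 ± 0.06 and Bgn at -0.36 ± 0.03, and this call ended in 10 of 23 alternatives (adjusted p of 0.00701 to 0.391), median-of-ratios factors (0.105) and TPM (0.0533) among them. Among 7 platelet and megakaryocyte markers tested 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.127). By camera this list was called higher in 2 of 22 alternatives (adjusted p of 0.0231 to 0.391). Pf4 and Ppbp, chemokines stored in platelet granules, rose from 521 ± 30.6 to 2639 ± 106 FPKM and from 11.8 ± 1.10 to 131 ± 11.3 FPKM.

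Here 17 of the 31 lists were called by camera, 12 higher and 5 lower. The 7 that held with an estimated correlation were glycolysis, other HIF targets, inflammatory genes, chemokines, NF-kB feedback genes, cholesterol synthesis and proliferation. Their adjusted p by camera was then 0.00477 for both other HIF targets and proliferation, and 0.00732 for chemokines. It was 0.014 for both inflammatory genes and cholesterol synthesis. NF-kB feedback genes, at 0.0382, and glycolysis, at 0.0438, lay close to the threshold. After rescaling to TPM interferon-stimulated genes counted 15 up and 6 down and reactive oxygen enzymes 12 up and 6 down, and both lists stayed called. After quantile normalization, which gives genes of equal rank equal values, the change of the highly ranked Lyz2 was 0.00 here and 0.06 against control, and neither was called.

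**Figure D3:**
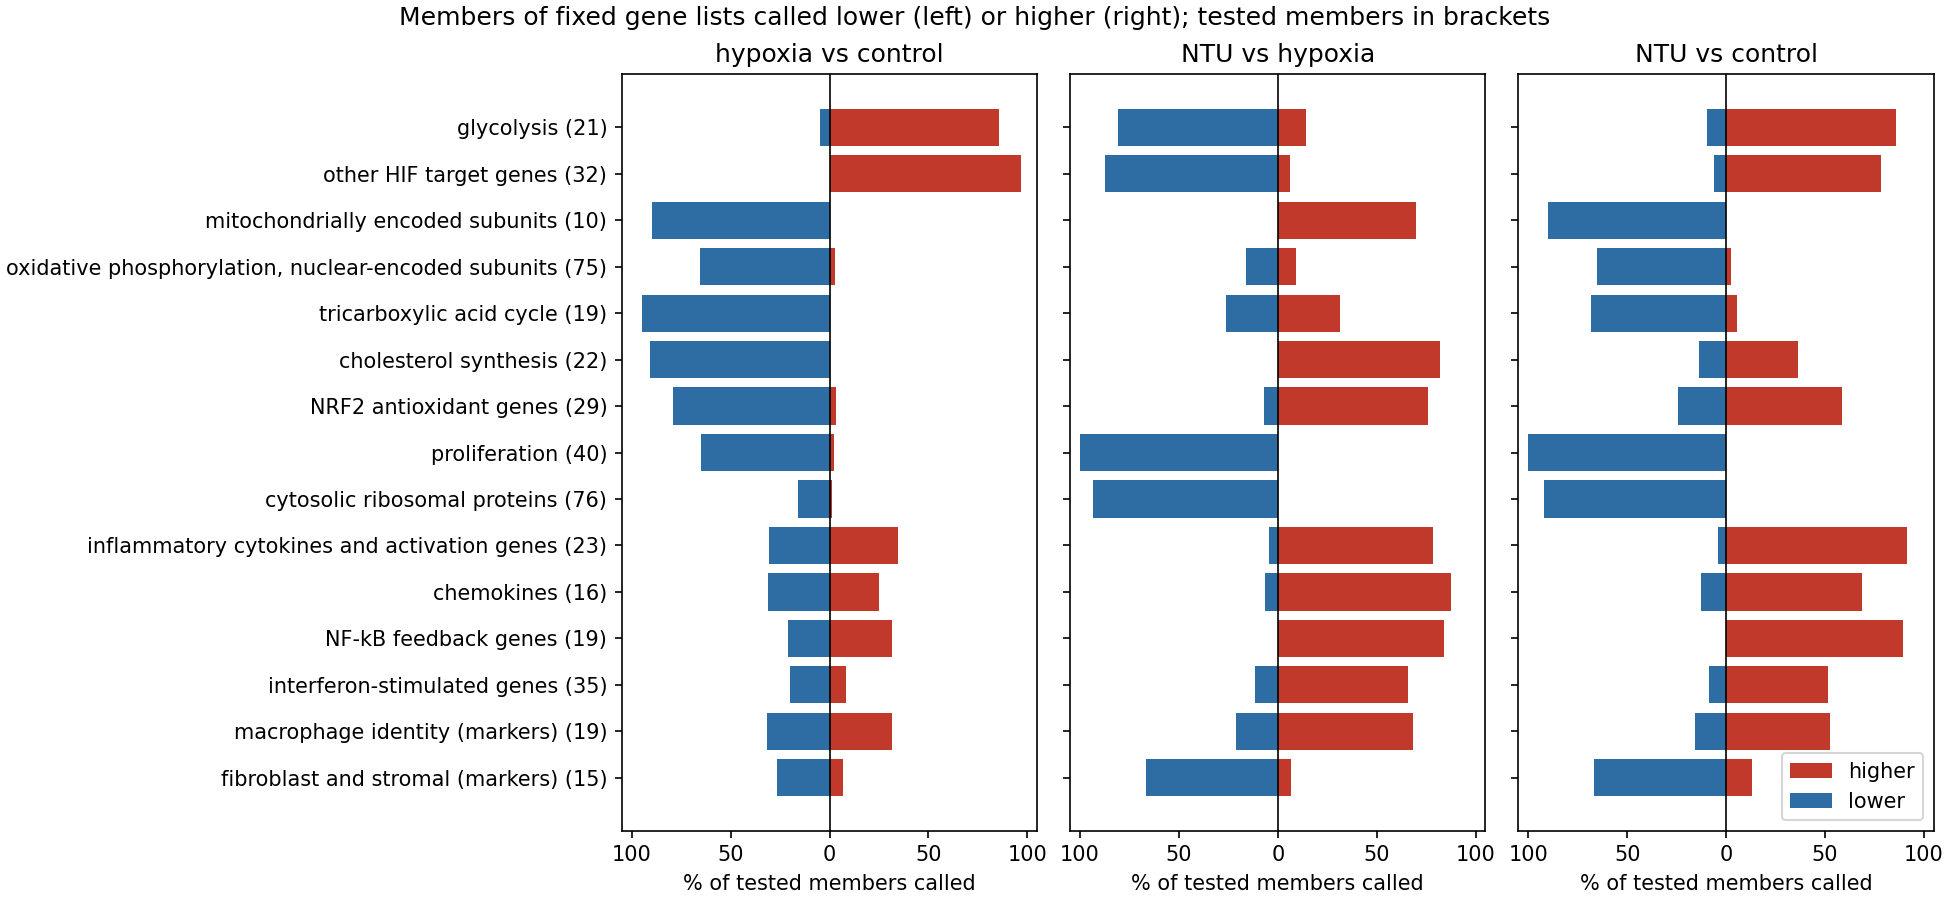
Percentage of the tested members of 15 fixed gene lists called lower (blue, left) or higher (red, right) in the 3 comparisons, with the number of tested members in brackets. Glycolysis and other HIF targets were mostly higher in hypoxia and mostly lower in NTU than in hypoxia, and all 40 proliferation genes were lower in NTU in both of its comparisons.

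The comparison of NTU with control shows how far the treated cells stood from untreated ones. Inflammatory genes stood far above control, most HIF targets and glycolysis genes stood above it, and genes of the cell cycle stood below it. Genes of the mitochondrial genome stood below it too, a call of the list that ended with an estimated correlation (adjusted p = 0.203) and held in the other 22 of 23 alternatives. Arg1 had the highest fold change, at 0.257 ± 0.120 FPKM in control and 558 ± 36.3 in NTU (log2 8.80 ± 0.07, SE, n = 3 per group). Lpl had the lowest, at 254 ± 4.5 and 15.4 ± 0.33 FPKM (log2 -3.96 ± 0.04). Vegfa stood at 17.7 ± 0.38 and 39.5 ± 1.1 FPKM (log2 1.11 ± 0.03).

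Between NTU and control 6830 genes, 56.9% of those tested, differed (limma, Benjamini-Hochberg adjusted p under 0.05), 2111 higher and 4719 lower, and 660 of them at least 2-fold, 320 higher and 340 lower. That number was 981 with a pseudocount of 0.1 (416 and 565), 918 after rescaling to TPM (346 and 572), 1028 by voom on recovered reads (424 and 604) and 663 with median-of-ratios factors (400 and 263). The share that was higher, 30.9%, was 51.9% with median-of-ratios factors, 45.2% after quantile normalization and 22.3% after rescaling to TPM. The 10 highest were Arg1, Saa3 (log2 6.95 ± 0.08), Cxcl3 (6.84 ± 0.08), Acod1 (6.14 ± 0.21), Serpinb2 (5.90 ± 0.07), Cxcl2 (5.49 ± 0.10), Il1b (4.82 ± 0.11), Slpi, the formyl peptide receptor Fpr1 (4.42 ± 0.09) and Clec4e. After Lpl and Pcp4l1 (-2.98 ± 0.10), the lowest were Stmn1 (-2.27 ± 0.05), the cyclin Ccnd1 (-2.26 ± 0.04), Ccnb2 (-2.22 ± 0.04), Cdkn2c, Id1 (-2.13 ± 0.10), Kif23, Nusap1 and Ankle1.

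Of 21 glycolysis genes 18 stood above control and 2 below (18 and 2 adjusted over the list alone; median 0.73, camera adjusted p = 1.87e-13), and of 32 other HIF targets 25 above and 2 below (25 and 3 adjusted over the list alone; median 0.50, adjusted p = 1.87e-13). Examples were Pgk1 (1.21 ± 0.02), Pfkfb3 (2.34 ± 0.05), Slc2a1 (1.53 ± 0.04), P4ha2 (1.40 ± 0.03) and the oxidoreductase Ero1l (1.44 ± 0.04). Of the 18 glycolysis genes that rose in hypoxia 15 fell with the units and light, and 14 of those 15 still stood above control. Of the 31 other HIF targets that rose in hypoxia 28 fell, 22 of them to a level above control, 2 to a level below it and 4 to a level not called different from it, Ccng2 among these (-0.07 ± 0.04).

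Inflammatory genes rose in 21 of 23 cases and fell in 1 (21 and 1 adjusted over the list alone; median 1.24, adjusted p = 1.89e-15), chemokines rose in 11 of 16 and fell in 2 (11 and 2 adjusted over the list alone; median 1.02, adjusted p = 3.19e-09), and NF-kB feedback genes rose in 17 of 19 and fell in none (17 adjusted over the list alone; median 1.34, adjusted p = 1.89e-15). Interferon-stimulated genes rose in 18 of 35 cases and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 2.79e-05, adjusted p = 0.397 with an estimated correlation). Of 13 neutrophil markers 6 rose and 5 fell (6 and 5 adjusted over the list alone; adjusted p = 0.352), with Mmp8 at 3.45 ± 0.06, while Ngp fell by 1.64 ± 0.09 and Ltf fell by 1.62 ± 0.08. Of 7 platelet markers Pf4 rose by 2.28 ± 0.06 and Ppbp by 3.29 ± 0.11, and the other 5 were not called, though 2 of them were called lower after rescaling to TPM. Camera gave an adjusted p of 0.108 for the list, which was called in 1 of 22 alternatives (adjusted p of 0.0445 to 0.368). NRF2 antioxidant genes rose in 17 of 29 cases and fell in 7 (18 and 7 adjusted over the list alone; adjusted p = 1.18e-05, adjusted p = 0.211 with an estimated correlation), with Hmox1 at 1.32 ± 0.03 and Nqo1 at 0.30 ± 0.12 (adjusted p = 0.051). Nqo1 was called in 8 of 22 alternatives (adjusted p of 0.0102 to 0.172). Of 22 reactive oxygen enzymes 12 rose and 7 fell (12 and 8 adjusted over the list alone; adjusted p = 0.00079, adjusted p = 0.161 with an estimated correlation).

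Nuclear-encoded subunits of oxidative phosphorylation fell in 49 of 75 cases and rose in 2 (51 and 2 adjusted over the list alone; median -0.20, adjusted p = 0.000516, adjusted p = 0.0626 with an estimated correlation), with Ndufa4 at -0.77 ± 0.04 and Atp5a1 at -0.40 ± 0.02. The list stayed called lower under each scaling, but its counts moved, to 26 lower and 6 higher with median-of-ratios factors (median -0.07) and 60 lower and 1 higher after rescaling to TPM. Mitochondrially encoded subunits fell in 9 of 10 cases and rose in none (9 adjusted over the list alone; median -0.51, adjusted p = 0.00148, adjusted p = 0.203 with an estimated correlation). Genes of the tricarboxylic acid cycle fell in 13 of 19 cases, and Acod1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.0491, adjusted p = 0.224 with an estimated correlation; the median was -0.25 and the mean 0.06), a call that ended in 14 of 23 alternatives (adjusted p of 0.000343 to 0.224). All 40 proliferation genes fell (40 adjusted over the list alone; median -1.48, adjusted p = 9.92e-20), with Pcna at 230 against 82.5 FPKM. Ribosomal protein genes fell in 70 of 76 cases (73 adjusted over the list alone; median -0.30, adjusted p = 9.06e-13, adjusted p = 0.14 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 22 cases and fell in 3 (8 and 3 adjusted over the list alone; median 0.02, adjusted p = 0.0493, adjusted p = 0.22 with an estimated correlation), and this call ended in 13 of 23 alternatives (adjusted p of 0.0263 to 0.22); after rescaling to TPM the median was -0.06, with 6 up and 5 down.

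Macrophage markers rose in 10 of 19 cases and fell in 3 (10 and 3 adjusted over the list alone; adjusted p = 6.05e-05, adjusted p = 0.102 with an estimated correlation), with Adgre1 at 1.14 ± 0.02. Stromal markers fell in 10 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0556), Pdgfrb by -0.75 ± 0.04. They were called lower as a list in 5 of 23 alternatives (camera, adjusted p of 0.0092 to 0.396). Camera called 20 of the 31 lists, 14 higher and 6 lower. The 9 that held with an estimated correlation were glycolysis, other HIF targets, inflammatory genes, chemokines, NF-kB feedback genes, proliferation, lipid handling, autophagy and extracellular matrix. The last 3 are described under other observations. With the estimated correlation the adjusted p by camera was 0.00394 for other HIF targets and 0.00556 for proliferation. It was 0.0095 for each of glycolysis, inflammatory genes and chemokines, and 0.0267 for both NF-kB feedback genes and autophagy. Extracellular matrix, at 0.0393, and lipid handling, at 0.046, lay close to the threshold. With median-of-ratios factors 16 macrophage markers were higher and 3 lower, reactive oxygen enzymes counted 14 up and 2 down and NRF2 genes 19 up and 3 down; after rescaling to TPM the counts were 9 and 3, 11 and 10, and 14 and 8. These lists stayed called under both.

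Whether the units and light moved hypoxia-changed genes back was tested by counting genes called in both steps. Of the 1853 genes that rose in hypoxia 1044 (56.3%) fell in NTU against hypoxia and 327 rose further. Of the 3046 that fell in hypoxia 849 (27.9%) rose and 867 fell further. If the calls were independent, 609 and 549 genes would have gone in opposite directions, against the 1044 and 849 counted. By the same reckoning 334 would have risen further and 1000 fallen further, against the 327 and 867 counted. All these counts take changes of any size. A 2-fold minimum left far fewer opposite genes, as given in the part on processing below. Of the 1044 genes that rose and then fell, 532 were not called different from control in NTU, 194 stood above it and 318 below it. Of the 849 that fell and then rose, 442 were not called different from control, 262 stood above it and 145 below it. These fates are given for the deposited scaling only. With median-of-ratios factors 3051 genes in all were lower in NTU than in control, against 4719, and 3294 were higher, against 2111. Genes called in the same direction in both steps then numbered 959, against 1194, and opposite ones 1873, against 1893. Both steps use the same hypoxia libraries, which alone makes their fold changes go opposite ways. The covariance of the fold changes over genes was -0.0303, against -0.00607 in data simulated with no effect, while Pearson r was -0.20 and Spearman rho -0.23, against a simulated r of -0.50. With no effect, 100 simulations called 0.01 genes opposite on average and at most 1. Almost no gene can be called in both steps of such data, so this number cannot judge the counts of opposite genes. The excess was also counted with separate hypoxia libraries for the steps, 1 for one and 2 for the other, in the 6 possible divisions. A single hypoxia library has no spread of its own, so that step takes its spread from the other groups of the fit, and its calls are less certain. With fewer libraries per step 574 to 749 genes rose and then fell, 1.76 to 1.99 times the number under independence, and 453 to 570 fell and then rose, 1.44 to 1.79 times, against 1.72 and 1.55 times undivided. The covariance was then -0.0241 to -0.0193.

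**Figure D4:**
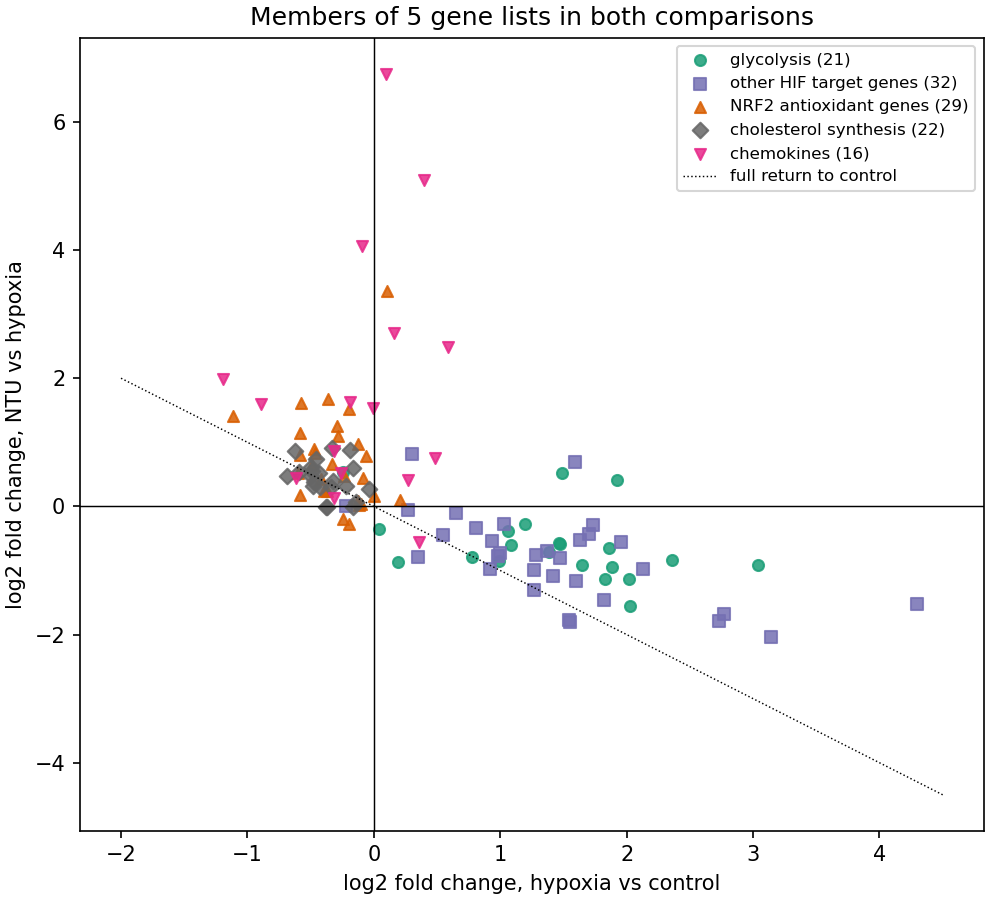
Log2 fold change of the members of 5 gene lists in hypoxia against control (horizontal axis) and in NTU against hypoxia (vertical axis), 1 point per gene, with the number of genes in brackets; the dotted line marks a full return to the control level. Most HIF targets and glycolysis genes lie at the lower right and above the line, cholesterol synthesis and NRF2 genes mostly at the upper left, and chemokines mostly above 0 on the vertical axis.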

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

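Limma voom on recovered reads and the fit of protein-coding genes were chosen after the results were seen; all other alternatives were fixed before. The counts of changed genes, changed lists and genes changed in opposite directions gave 181 alternative values, of which 174 lay within 1.5 times the reported count. The other 7 came from stricter criteria. A 2-fold minimum left 138, 562 and 660 genes (hypoxia against control, NTU against hypoxia and NTU against control) and 33 genes changed in opposite directions. An estimated correlation left 6, 7 and 9 lists in the same order. Without 1 library the 3 gene counts were 4001 to 4800, 5496 to 6133 and 6248 to 6824, the list counts 11 to 15, 16 to 18 and 18 to 20, the F test 7559 to 7863 and the opposite genes 1515 to 1763. Voom called 5331, 6366 and 7072 genes, and the protein-coding fit 4953, 5939 and 6581.

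With the replicate block 4801, 6106 and 6833 genes, 11, 17 and 19 lists, 8045 genes changed among the 3 groups and 1864 opposite genes were called. Same-number libraries correlated at -0.0251 to 0.0677 after group means were removed (9 pairs), and different-number ones at -0.0766 to 0.054. In both other groups 3 libraries correlated best with their own number. Between control and hypoxia every same-number pair (0.0294 to 0.0677) lay above every other pair (at most 0.0106), which was not so for pairs with NTU. Whether the numbers pair the samples thus stays open. Of the 7436 alternative values of named genes that were called, 7332 kept direction and call, 104 kept the direction but were no longer called and none changed direction. Named genes not called became called in 22 values in the direction reported and in 1 in the other. The value for Fth1, hypoxia vs control was not called after quantile normalization (-0.06, adjusted p = 0.826) or with no filter on low values (adjusted p = 0.0949), with a range of 3.5e-11 to 0.826. The value for Txnip, NTU vs hypoxia was not called (0.01, adjusted p = 0.713), but was called lower after rescaling to TPM (-0.12, adjusted p = 0.0116) and higher with median-of-ratios factors (0.10, adjusted p = 0.017), with a range of 0.0116 to 0.956, so its direction rests on the scaling. Of 2136 alternative list values 2035 stayed on the same side of the threshold, 60 were no longer called and 41 became called. The camera direction turned in none of the 1104 alternatives of called lists and in 33 of the 1032 of lists not called, none of those past the threshold, and the list median changed sign in 4 and 59. Depth limits genes near 1 FPKM, with a median of 60.7 reads per library. The causes of the changes were not tested beyond this.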

Other observations

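The test on the list of collagen-producing cells was written before its values were seen; the other tests in this part were chosen after the result was seen. Several gene groups not described above changed. Lysosome genes rose in 16 of 42 cases and fell in 7 in hypoxia against control (17 and 7 adjusted over the list alone; camera adjusted p = 0.00467, adjusted p = 0.348 with an estimated correlation; 22 and 2 after TPM, 23 and 2 with median-of-ratios factors) and rose in 22 and fell in 8 in NTU against hypoxia (25 and 9; adjusted p = 0.000125, adjusted p = 0.148 with an estimated correlation), where TPM turned the median from 0.13 to -0.01 and the counts to 12 up and 17 down. Against control 26 rose and 8 fell (27 and 8; adjusted p = 2.71e-07, adjusted p = 0.0755 with an estimated correlation), with the cathepsins Ctsz (1.01 ± 0.03) and Ctsl (0.75 ± 0.03). Lipid handling genes went both ways in NTU against hypoxia, 10 of 24 up and 7 down (11 and 7; median 0.06, and -0.05 with 8 up and 9 down after TPM, adjusted p = 0.0173, adjusted p = 0.0771 with an estimated correlation). Against control 12 rose and 6 fell (12 and 7; adjusted p = 0.00324), with the cholesterol exporter Abca1 at 18.1 against 77.2 FPKM and the lysosomal lipase Lipa at 575 ± 12.5 against 280 ± 2.66 FPKM. Autophagy genes rose in 12 of 24 cases and fell in 3 in NTU against control (12 and 3; 9 and 5 after TPM; adjusted p = 0.000441), Sqstm1 by 0.85 ± 0.03 and Bnip3 by 1.09 ± 0.06. Matrix and remodelling genes rose in 18 of 32 cases and fell in 7 (18 and 8; adjusted p = 2e-05), the protease Mmp8 by 3.45 ± 0.06 and Mmp14 by 1.56 ± 0.03, while the growth factor Igf1 changed by -1.34 ± 0.03. In hypoxia against control neither list was called, nor was lipid handling (adjusted p = 0.058 for autophagy, 0.0772 for matrix and 0.732 for lipid). Autophagy was called higher there in 11 of 23 alternatives (adjusted p of 0.0187 to 0.154), TPM, median-of-ratios and quantile scaling among them.

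Iron handling genes rose in 9 of 15 cases and fell in 4 in NTU against hypoxia (9 and 4 adjusted over the list alone; adjusted p = 0.00295, adjusted p = 0.0676 with an estimated correlation), the metal transporter Slc11a1 by 0.97 ± 0.03, and were not called against control (6 up and 6 down, 7 and 3 with median-of-ratios factors, adjusted p = 0.125). Stress response and unfolded protein genes fell in 20 of 30 cases and rose in 3 in NTU against control (20 and 4; adjusted p = 0.0192, adjusted p = 0.24 with an estimated correlation), with the chaperone Hspa5 at -0.57 ± 0.03 and the serine synthesis enzyme Psat1 at -0.96 ± 0.03. Immediate early genes rose in 9 of 18 cases and fell in 5 in hypoxia against control (9 and 5; adjusted p = 0.0139, adjusted p = 0.373 with an estimated correlation), Jun by 0.97 ± 0.03, while Fos changed by -0.58 ± 0.04. In NTU against hypoxia, besides lists given above, no call was made for autophagy (8 of 24 up and 5 down, 5 and 11 after TPM, adjusted p = 0.212), matrix and remodelling (14 of 32 up and 14 down, 0.0568), stress response (4 of 30 up and 15 down, 9 and 14 with median-of-ratios factors, 0.106) or immediate early genes (5 of 18 up and 9 down, 0.576). Matrix genes were called there in 2 of 23 alternatives (adjusted p of 0.0169 to 0.254) and stress response genes in 4 (0.0072 to 0.404), TPM among them for both. Nor was a call made for heat shock genes (2 of 18 up and 9 down, adjusted p = 0.0671), phagocytosis receptors (9 of 26 up and 13 down, 0.705), p53 targets and cell death (9 of 25 up and 10 down, 0.504), antigen presentation (5 of 16 up and 5 down, 0.62) or osteoclast markers (3 of 7 up and 2 down, 0.155). The medians of phagocytosis and p53 genes were -0.12 and -0.02 there and the means 0.06 and 0.05. Lists not called in hypoxia against control included interferon-stimulated genes (3 of 35 up and 7 down, adjusted p = 0.779), reactive oxygen enzymes (4 of 22 up and 10 down, 4 and 5 after TPM, 0.353) and ribosomal proteins (1 of 76 up and 12 down, 0.555). The balance of the ribosomal proteins turned to 11 up and 2 down after TPM and to 8 up and 6 down with median-of-ratios factors. In NTU against hypoxia after TPM p53 genes counted 4 up and 15 down and antigen presentation 2 up and 9 down, and heat shock genes were called lower in 2 of 23 alternatives (adjusted p of 0.00701 to 0.289). Fas, a death receptor, rose from 2.19 to 14.2 FPKM, the opsonin Gas6 changed by -1.13 ± 0.04, and the class II gene H2-Ab1 stood at 14.0 FPKM in control, 27.6 in hypoxia and 25.1 in NTU.

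Type I collagen and Sparc were abundant in all 3 groups of cells labelled as macrophages, and a candidate explanation is that the cultures held collagen-producing cells of another type. Of 16 genes known from such cells, in a list made after other values had been seen and before its own were, 14 stood at 10 FPKM or more in each group mean, with Acta2 at 1001, 719 and 619 FPKM in control, hypoxia and NTU, Serpinh1 at 302, 317 and 227 and Lox at 218, 355 and 269. Tagln, at 0.551, 0.492 and 0.402 FPKM, and Col4a1, at 9.61 in NTU, were the exceptions, and Dcn and Lum were low, so the explanation is consistent with this test while the kind of cell stays open. Libraries made from chondrocytes, as the series title could be read, are argued against, since 1 of 20 chondrocyte markers (Fmod) and all 19 macrophage markers reached 10 FPKM in a group mean. Expression of these genes by the macrophages themselves stays open and untested, because the libraries mix all cells.

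Pf4 and Ppbp, known from platelets, were higher in NTU than in hypoxia, and the units carried a platelet membrane coat. Platelet RNA from the coat is argued against, since 0 of the 5 other tested platelet markers rose and the highest upper end of their log2 fold changes was 0.40, against 2.34 for Pf4. Both genes lie in a run of chemokine genes, and the other 4 tested genes of that run rose too (Cxcl1 by 4.07 ± 0.10, Cxcl2, Cxcl3, and Cxcl5 by 2.70 ± 0.15), while 2 of the 10 nearest tested genes outside it did. Since 10 of 12 tested chemokines elsewhere rose as well, a shared response of these neighbours cannot be told apart from a rise of chemokines in general.

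Inflammatory, chemokine and NF-kB feedback genes were higher in NTU than in hypoxia, 48 of 58 tested members. More neutrophils in the NTU cultures stay open, since 7 of 13 tested markers rose and 5 fell. A larger share of collagen-producing cells as the whole cause is argued against, since of 30 tested stromal and collagen-producing cell genes 4 rose and 18 fell, and at most 6 rose under any scaling. Scaling between libraries as the whole cause is argued against too, as all 48 were still called higher under TPM, median-of-ratios and quantile scaling. A response of the cells to the units with light is left as a hypothesis beside a change in cell types, and whether the particles, their coat, a contaminant of the preparation or light was responsible, and in which cells, was not tested, since no group received them apart.

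The 6 libraries of each comparison allow 10 splits into 3 against 3, too few for a share under 0.05. The real splits gave 4899, 6106 and 6830 genes and were the only 1 of 10 with as many; the highest other split gave 0 in each. Among 100 splits of all 9 libraries into 3 groups, the real one alone gave as many as 8126 genes by the F test, and the highest other gave 3914. A share of 1 of 100 is the smallest these splits can give, so a random division of these libraries seldom gives such a count. Every other split puts libraries of different groups together, which widens the spread within its groups. The low counts of the other splits therefore do not measure how many calls are false. The splits cannot tell a treatment from a difference between cultures or batches that coincides with the groups.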
